A study of Mus musculus with 24 samples.

How the data were processed

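The authors deposited a table of raw counts per gene for 23 libraries and 3 tables of results, each of chow against 1 oil diet. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with STAR 2.7.1a to mm39 and counted with HTSeq 0.9.1, and DESeq2 and DESeq were used. The deposited tables of results hold a log2 fold change of chow over the oil diet with its log2 standard error, a score (the Wald statistic), and a p-value before and after adjustment. Their sign was turned so that positive means higher in the oil diet. The strand setting is not given in the sources used here. The labels name 24 samples, and SFO_4, which the submitters describe as an extreme outlier with possible contamination, has no column in the count table and was left out. The table holds 13686 genes, none of them mitochondrial, and the smallest total count of a gene is 51. The reference used here for symbols is another build than that of the counts, so only symbols were matched, and 13407 were found.

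Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. filterByExpr kept 11971 genes, which hold 99.9% of the counts. Libraries were scaled by TMM, the 4 diets were fitted together with diet as the only term, and 7 comparisons were tested with edgeR's robust quasi-likelihood F test. Adjusted p is Benjamini-Hochberg over the tested genes of a comparison, with a threshold of 0.05. Log2 CPM used a prior count of 2. Genes detected were compared after thinning each library to 5e+06 counts, with an exact two-sided permutation test over all splits of the libraries of 2 groups.

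The comparisons, the 30 gene lists, the rule for naming genes and most of the other settings compared were fixed before the data were examined. Named were the 8 largest rises and falls in each comparison with chow and in CSO against the mean of OO and SFO, and 3 each way between pairs of oils. These needed an adjusted p under 0.05, a mean log2 CPM of at least 1 and every library of the first group on the same side of the mean of the others, and predicted genes and pseudogenes were skipped. Added to them were up to 4 called members per list with the smallest adjusted p (up to 2 of the most expressed where none was called) and 15 genes of lipid metabolism named in advance, and some of the genes that met this rule are not reported here. Lists with at least 5 tested members, 25 of the 30, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation, with fry, with a replicate block and with DESeq2's size factors. T and NK cell (3 tested members), neutrophil (1), erythroid (2), adipocyte (2) and exocrine pancreas (2) markers were too few to test. Genes with 0 counts over a group are given as a bound against a floor of 3 counts over that group, and genes with 1 to 3 counts as a ratio with a 95% counting interval. Members of multigene families such as Cyp3a, Cyp4a, Cyp2c, Gstm, Gsta, Ces, Saa, Mup and Acot share sequence, and their separate counts are uncertain.

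Those other settings were DESeq2's size factors in edgeR, library totals without a composition factor, DESeq2's Wald test, limma voom with sample quality weights, no filter, a filter of at least 10 counts in 5 libraries, only the diets of the comparison, the replicate number as a block, an absolute log2 fold change of at least 1, and each library left out in turn. Added after the data were seen were leaving out the 4 libraries with Acta1 over 100 CPM, the clock score as a covariate, thinning to the shallowest library, and only the diets of the comparison with the genes and composition factors of all libraries. Overlap between oil diets was compared with independent lists, with 20 simulations of unchanged groups that share the chow libraries, and with the chow libraries split 3 and 3.

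The procedure was run on simulated counts with 200 changed genes among 11971. Of 100 genes changed 2-fold, 14, 25, 20 and 26 were recovered for CSO, OO and SFO against chow and CSO against the mean of OO and SFO, and of 100 changed 4-fold, 53, 52, 46 and 63. Among genes with a mean log2 CPM of at least 6 the shares were 57.1%, 65.2%, 70.0% and 88.9% at 2-fold and 100%, 94.4%, 95.5% and 100% at 4-fold. Unchanged genes made up 2.82%, 2.47%, 0% and 2.04% of the calls. DESeq2 called 24 unchanged genes of 110 calls, 28 of 126, 19 of 112 and 21 of 135 on the same data, and voom 1 of 51, 3 of 70, 3 of 65 and 4 of 86. The shifted list was recovered each time, and 0, 1, 0 and 0 of the 24 other lists were called. Genes were simulated independently of each other, so this does not show how often lists of correlated genes are called wrongly.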

Results

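Liver messenger RNA was measured by 3′ tag sequencing (QuantSeq, which counts tags at the 3′ end of transcripts) in male C57BL/6 mice, a common inbred laboratory strain. The mice were kept for 6 weeks on chow or on a diet made with cottonseed oil (CSO), olive oil (OO) or safflower oil (SFO). The labels name 6 samples per diet, and the count table holds 6 chow, 6 CSO, 6 OO and 5 SFO libraries. Library totals ran from 5.43e+06 to 1.49e+07 counts. Nothing in the labels says more than that these are separate samples, so p-values measure the spread between these samples, which may be technical. Values below are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11971 genes, unless they are given as CPM (counts scaled to a common library total, mean ± SD).

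The libraries differed by group in what they held. At an equal depth of 5e+06 counts, the OO libraries had 10934 ± 403 detected genes (n = 6), against 11962 ± 105 in chow, 12012 ± 409 in CSO and 11644 ± 316 (n = 5) in SFO. The difference between OO and chow had an exact two-sided permutation p of 0.00216, the smallest that 924 splits allow (adjusted p = 0.00649 over 3 comparisons). By the same exact test SFO against chow gave 0.0455 (adjusted p = 0.0682) and CSO against chow 0.786. Within OO, library OO 3 stood apart, with the fewest detected genes (10310), the lowest median correlation with the other libraries (0.797) and the lowest composition factor (0.811). On the first principal component it was at 169, and OO 2, the next highest, at 60.9. Transcripts of skeletal muscle stood out in 4 libraries. Acta1, the skeletal muscle actin, was at 460 CPM in chow 3, 887 CPM in chow 4, 186 CPM in chow 5 and 314 CPM in CSO 1. It was at 27.6 CPM in chow 6 and at or below 15.6 CPM in every other library. A clock score chosen after values per library were seen, the log2 ratio of Per2, Per3, Tef, Dbp and Ciart to Clock, Arntl, Npas2 and Nfil3, was 3.92 ± 0.64 in CSO (n = 6), against 1.48 ± 1.76 in chow, 1.21 ± 1.54 in OO and 1.70 ± 2.37 in SFO.

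**Figure D1:**
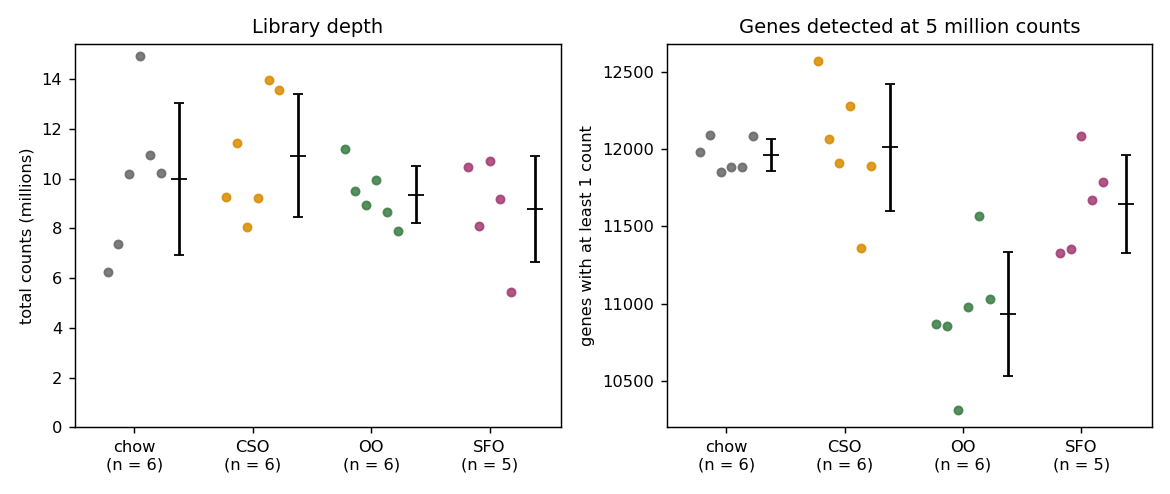
Total counts per library (left) and genes with at least 1 count after thinning each library to 5e+06 counts (right, axis not from 0), by diet; each point is a library and the black bars are the mean and SD. Detected genes averaged 10934 in OO against 11962 in chow.

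**Figure D2:**
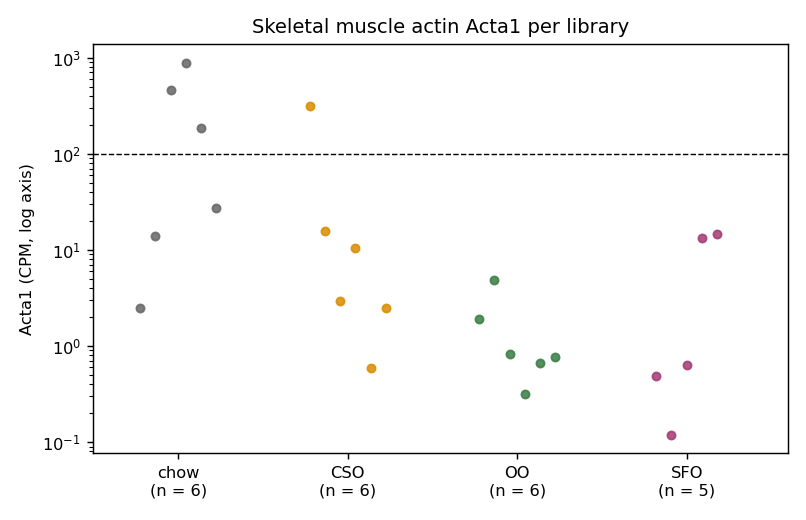
Acta1 in CPM on a log axis, by diet; each point is a library and the dashed line marks 100 CPM. Chow 3, chow 4, chow 5 and CSO 1 lie above the line.

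Against chow, 49 genes changed in CSO livers (25 higher, 24 lower), 316 in OO livers (206 higher, 110 lower) and 100 in SFO livers (59 higher, 41 lower). Without the 4 libraries with muscle transcripts, a choice made after the data were seen that leaves 3 chow libraries, these counts were 14, 26 and 34. Between the oils, 87 genes differed between CSO and the mean of OO and SFO (41 higher, 46 lower in CSO) and 130 between CSO and OO (30 higher, 100 lower in CSO), while 59 differed between CSO and SFO (34 higher, 25 lower in CSO) and 127 between SFO and OO (32 higher, 95 lower in SFO). Without the 4 libraries these were 42, 40, 39 and 37. The authors' deposited tables of the comparisons with chow hold 98 genes for CSO, 683 for OO and 205 for SFO at an adjusted p under 0.05. They include, in the same direction, 49 of the 49, 315 of the 316 and 100 of the 100 genes called here.

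**Figure D3:**
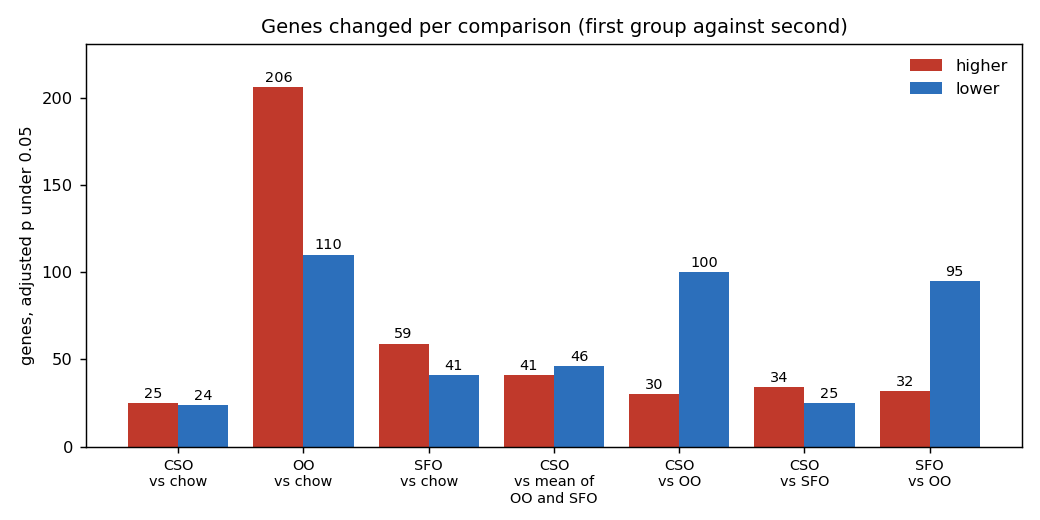
Number of genes with an adjusted p under 0.05 in each comparison, split into genes higher (red) and lower (blue) in the first-named diet; the axis starts at 0. OO against chow has the highest bar, with 206 genes higher.

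The same 14 genes were called against chow in all 3 oil diets. Of these, 8 were higher and 6 lower. Apoa4, an apolipoprotein of triglyceride-rich particles, was at 156 ± 25.8 CPM in chow (n = 6) and at 634 ± 88.5 in CSO (n = 6), 885 ± 451 in OO (n = 6) and 910 ± 345 in SFO (n = 5). Apoa1, the main apolipoprotein of high-density lipoprotein, Fads2, a desaturase of polyunsaturated fatty acid synthesis, Msmo1, a sterol synthesis enzyme, Mat1a, which makes S-adenosylmethionine, Rnase4, a ribonuclease, both chosen after their values were seen, and Serpina3n and Cyp2d40 also rose. Cyp3a11, a main drug-metabolising cytochrome P450, fell from 5219 ± 708 CPM in chow to 766 ± 194 in CSO, 861 ± 246 in OO and 716 ± 331 in SFO. Csad, an enzyme of taurine synthesis, fell by 1.57, 1.84 and 1.91 on the log2 scale in CSO, OO and SFO. Gstm1, a glutathione transferase, fell by 1.40, 1.09 and 1.60. Cyp2c29, Ces2a, a carboxylesterase, and Ephx1, the microsomal epoxide hydrolase, fell in all 3 as well. Without the 4 libraries with muscle transcripts, Serpina3n, Cyp2d40, Ephx1 and Msmo1 lost the call in CSO (adjusted p = 0.777, 0.289, 0.229 and 0.144). Their fold changes kept their direction. Each comparison with chow is between whole diets. It does not separate the oil from the rest of the diet, also for genes shared by all 3.

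Pairs of oil diets shared calls in the same direction. CSO and OO shared 16 higher and 8 lower genes, where independent lists of these sizes would share 0.430 and 0.221, and 1 gene went opposite ways. CSO and SFO shared 8 higher and 11 lower genes (0.123 and 0.0822 for independent lists), and OO and SFO shared 27 higher and 19 lower genes (1.02 and 0.377). The same 6 chow libraries stand in all these comparisons, and 20 simulations of unchanged groups against them gave 0 shared calls. The simulated value leaves out any effect of diet and that of independent lists leaves out the shared chow libraries, so neither shows how much of the overlap the shared libraries made. With the chow libraries split 3 and 3, the median shared counts were 3 higher and 5 lower for CSO and OO, 1.5 and 7.5 for CSO and SFO, and 6 and 7 for OO and SFO. Independent lists of the sizes called in the splits would share medians of 0.0144 and 0.0171, 0.00931 and 0.0200, and 0.0505 and 0.0383. Each comparison then has 3 chow libraries in place of 6, so these counts are not on the same footing as those above. Across genes, which are not independent replicates, fold changes had Pearson r of 0.445, 0.493 and 0.447 for these pairs, against simulated means of 0.502, 0.472 and 0.470. With chow split 3 and 3 the median r was 0.122, 0.129 and 0.183. Among genes with a mean log2 CPM of at least 6, r was 0.492, 0.470 and 0.607, against simulated means of 0.499, 0.476 and 0.477. Over all tested genes the covariances were 0.426, 0.382 and 0.581, against simulated covariances of 0.321, 0.321 and 0.321. Over the genes with a mean log2 CPM of at least 6 they were 0.0710, 0.0608 and 0.110, against 0.0319, 0.0321 and 0.0324.

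**Figure D4:**
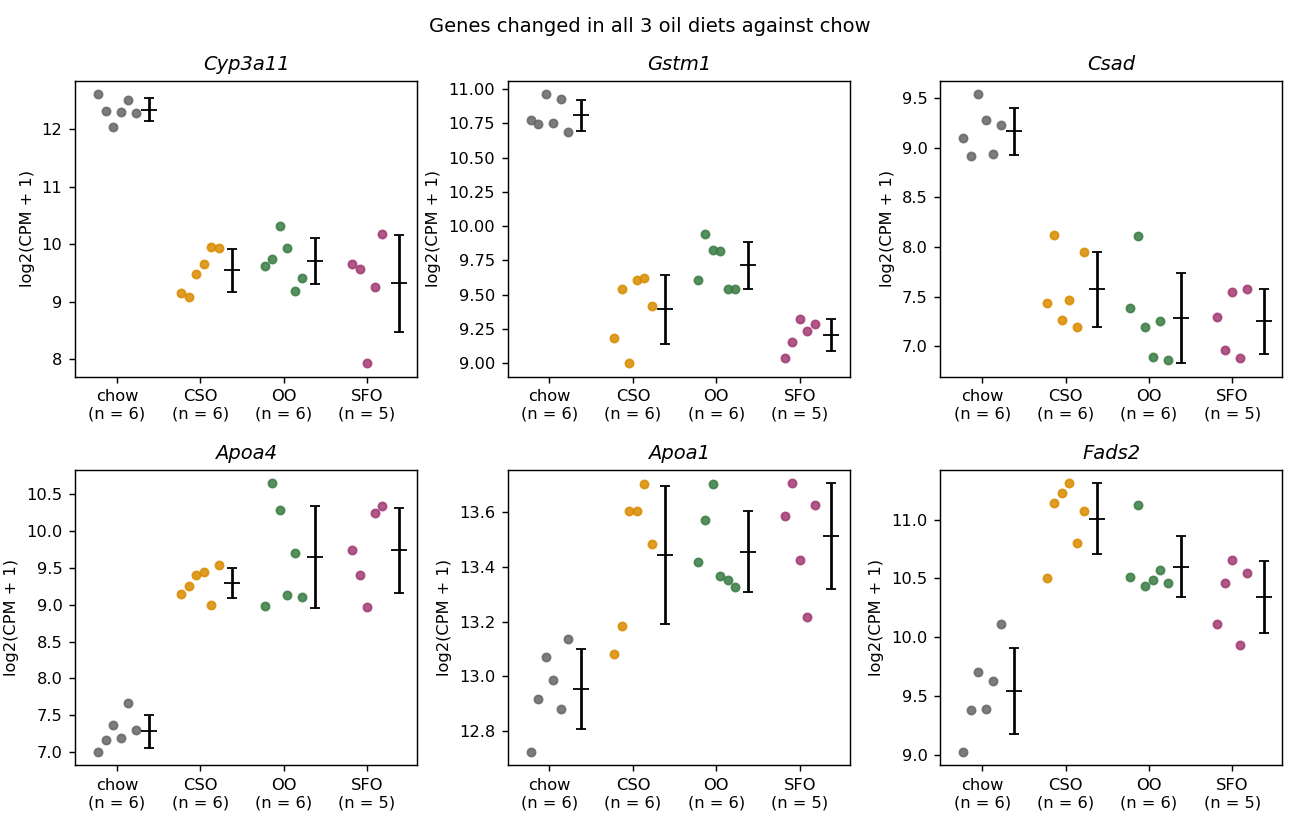
Log2(CPM + 1) of 6 of the genes that changed in all 3 oil diets, by diet, with axes not from 0; each point is a library and the black bars are the mean and SD. Cyp3a11, Gstm1 and Csad are lower, and Apoa4, Apoa1 and Fads2 higher, in the oil diets than in chow.

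CSO livers, set against chow to ask what the cottonseed oil diet changes, had higher transcripts of the desaturases Fads2 and Fads1 and of cholesterol genes and lower transcripts of xenobiotic metabolism genes and NRF2 targets. Fads2 rose by 1.46 ± 0.16 (adjusted p = 6.78e-08) and Fads1, the companion desaturase, by 0.87 ± 0.13 (adjusted p = 7.11e-05). Of the 19 measured members of the fatty acid synthesis list, these 2 rose and none fell. Within the list, 6 rose and 1 fell adjusted over the list alone (median 0.41, camera adjusted p = 2.60e-09, adjusted p = 0.0508 with an estimated correlation). All 24 measured members of the cholesterol synthesis and uptake list had a positive fold change. Only Msmo1 rose over all genes (0.96 ± 0.18), but 12 rose adjusted over the list alone (median 0.56, camera adjusted p = 7.45e-20, adjusted p = 0.00391 with an estimated correlation). Of 23 targets of the fatty acid receptor PPAR alpha, 3 rose and none fell, among them Aldh3a2, a fatty aldehyde dehydrogenase (0.84 ± 0.17), and Cpt1a, which admits fatty acids to mitochondria (0.55 ± 0.14). Within the list, 5 rose adjusted over the list alone (camera adjusted p = 5.95e-06, adjusted p = 0.0508 with an estimated correlation). The 16 mitochondrial fatty acid oxidation genes had 0 calls over all genes and 2 rises adjusted over the list alone (median 0.30, camera adjusted p = 5.95e-06, adjusted p = 0.0159 with an estimated correlation). The clock score given above was also highest in CSO.

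Of 25 genes of the xenobiotic metabolism list (targets of the receptors CAR and PXR), 5 fell in CSO, 1 rose and 19 did neither. Within the list, 9 fell and 2 rose adjusted over the list alone (median -0.47, camera adjusted p = 5.01e-15, adjusted p = 0.00109 with an estimated correlation). Cyp3a11 fell by 2.77 (SE 0.28), Gstm1 by 1.40 (SE 0.12), Cyp2c29 by 1.32 (SE 0.15) and Ces2a by 1.29 (SE 0.14), while Por, the electron donor of cytochromes P450, rose by 0.77 ± 0.19. Of 16 targets of the oxidative stress factor NRF2, Gclc, the catalytic subunit of glutathione synthesis (-0.95 ± 0.15), and Ephx1 (-0.96 ± 0.17) fell and none rose. Within the list, 3 fell adjusted over the list alone (median -0.56, camera adjusted p = 9.15e-07, adjusted p = 0.00120 with an estimated correlation). Outside these lists, Slc30a10, a manganese exporter, fell by 1.80 (SE 0.33), Slco2a1, a prostaglandin transporter, by 1.48 (SE 0.29), Cyp3a59 by 2.40 (SE 0.50) and Elovl3, a fatty acid elongase, by 1.71 (SE 0.36). Gbe1, the glycogen branching enzyme, rose by 0.99 ± 0.20, Fabp2 by 1.55 ± 0.36 and Slc16a12 by 1.01 ± 0.24, and Acsl4, an acyl-CoA synthetase, rose as well.

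Of the 29 called genes named for CSO against chow, 11 lost the call when some library was left out, namely Fabp2, Cyp2d40, Slc16a12, Acsl4, Elovl3, Cpt1a, Pcx, Nr1d1, Serpina3n, Cyp2e1 and Gulo. With the clock score as a covariate 14 of the 29 lost it, and without the 4 libraries with muscle transcripts 16 did. With 3 chow libraries left, the fold changes of these 16 kept their direction and about their size, and their SE grew. Gbe1 was then at 1.03 ± 0.27, Fabp2 at 1.94 ± 0.50 and Serpina3n at 0.65 ± 0.23 (0.78 ± 0.18 with all libraries). The count of 49 became 26, 29, 25 and 29 without chow 1, 2, 3 and 4, and 31, 28, 23, 30 and 22 without CSO 1, 3, 4, 5 and 6. It became 198 with only the chow and CSO libraries in the fit, 49 of them shared.

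OO livers, compared with chow, had higher transcripts of fatty acid, cholesterol, lipoprotein and bile acid metabolism. Srebf1, the transcription factor of fatty acid synthesis, rose by 1.37 ± 0.23 (adjusted p = 0.000787), Fasn, the fatty acid synthase, by 1.37 ± 0.28 (adjusted p = 0.0137), Elovl5, an elongase, by 1.06 ± 0.14 (adjusted p = 1.09e-06) and Fads1 by 0.94 ± 0.13. Of 19 fatty acid synthesis genes, 8 rose and none fell. Within the list, 13 rose adjusted over the list alone (median 0.62, camera adjusted p = 7.98e-15, adjusted p = 0.0182 with an estimated correlation). Of the 24 cholesterol genes, 9 rose and none fell, among them Hmgcs1 (1.07 ± 0.21), Lss (1.38 ± 0.28), Sqle (0.98 ± 0.22) and Sc5d (0.77 ± 0.14). Within the list, 16 rose adjusted over the list alone (median 0.53, camera adjusted p = 7.98e-15, adjusted p = 0.0182 with an estimated correlation). Of 22 lipoprotein genes 5 rose and none fell, including Apoa4 (2.50 ± 0.28), Abca1 and Scarb1, cholesterol transporters (both 0.66). Within the list, 8 rose adjusted over the list alone (camera adjusted p = 4.10e-07, adjusted p = 0.0182 with an estimated correlation). Of 17 bile acid genes, Hsd3b7, a bile acid synthesis enzyme (0.82 ± 0.13), Akr1c6 (0.64 ± 0.12), Abcb11, the bile salt export pump (0.59 ± 0.14), and Slco1b2 (0.50 ± 0.12) rose and none fell. Within the list, 9 rose adjusted over the list alone (camera adjusted p = 2.95e-05, adjusted p = 0.0450 with an estimated correlation).

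Pericentral hepatocyte genes also rose in OO, 5 of 16 with none fallen and 8 adjusted over the list alone (median 0.44, camera adjusted p = 1.36e-06, adjusted p = 0.0341 with an estimated correlation). Among them, Gulo, a vitamin C synthesis enzyme, rose by 0.96 ± 0.14, Lect2 by 1.34 ± 0.25 and Rgn by 0.65 ± 0.12. The rise was not particular to OO, as Gulo (0.58 ± 0.14) and Cyp2e1 (0.64 ± 0.14) were also called higher in CSO against chow. Of 25 xenobiotic genes, 5 fell and 1 rose in OO. Within the list, 12 fell and 3 rose adjusted over the list alone (median -0.51, camera adjusted p = 1.36e-06, adjusted p = 0.0257 with an estimated correlation). Cyp3a11 was at -2.60 ± 0.28, Ces2a at -1.21 ± 0.14 and Gstm1 at -1.09 ± 0.12. Acute phase genes rose in 7 of 23 cases and fell in none. Within the list, 9 rose adjusted over the list alone (median 0.52, camera adjusted p = 1.23e-07, adjusted p = 0.149 with an estimated correlation). Their mean level ran from 5.55 to 7.04 log2 CPM over the OO libraries. Of 20 interferon response genes, the interferon-inducible GTPases Irgm1 (1.16 ± 0.25), Ifi47 (1.70 ± 0.37) and Igtp (1.48 ± 0.39) and the factor Irf1 (1.18 ± 0.33) rose and Mx1, chosen after its values were seen, fell, the same counts adjusted over the list alone (camera adjusted p = 0.00149, adjusted p = 0.0541 with an estimated correlation). Of the 23 PPAR alpha targets, Acot1, an acyl-CoA thioesterase (-1.98 ± 0.50), and Pex11a, a peroxisome division factor (-0.81 ± 0.21), fell and none rose. Within the list, 5 fell and 1 rose adjusted over the list alone (median -0.07, mean -0.55, camera adjusted p = 0.0145, adjusted p = 0.269 with an estimated correlation). Other large rises were Slc10a2, a bile acid transporter (2.08 ± 0.39), Slc22a7, an organic anion transporter (2.17 ± 0.44), Serpina7, the thyroxine-binding globulin, Rnd1 (2.62 ± 0.71), Adgrv1 (2.36 ± 0.68) and Alg2 (2.12 ± 0.59). With 1 library left out, Rnd1 and Alg2 fell to 1.13 or below and Adgrv1 to 1.93. Rnd1 was at 133 CPM in OO 3 and Alg2 at 122 CPM in OO 2.

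The largest falls in OO were in Tuba8, a tubulin, and in skeletal muscle genes. Tuba8 had 0 counts in all 6 OO libraries and was at least 102-fold lower than in chow (floor of 3 counts over the group). It was at 2.34, 5.12 and 8.16 CPM in chow 1, 2 and 6, and lost the call without the 4 libraries with muscle transcripts (adjusted p = 0.0792). Its fitted difference, which rests on 0 counts in OO, stayed about as large (-8.61 ± 2.19 against -8.96 ± 1.95 with all libraries). The muscle genes were highest in chow 3, 4 and 5 among the chow libraries. Nrap had 2 counts in the OO group. This is a ratio of 883 with a counting interval of 244 to 7293. Pgam2 had 1 count, a ratio of 556 (99.5 to 22004), and Myot 2 counts, a ratio of 509 (141 to 4206). Actn3, Mb and Myh7 were at 0.0731, 0.267 and 0.0928 CPM in OO, against 22.4, 63.7 and 22.7 CPM in chow. Without the 4 libraries they differed by -4.91 ± 2.02, -2.61 ± 1.68 and -3.74 ± 1.94 (adjusted p = 0.392, 0.671 and 0.536), and Pgam2 by -0.95 ± 2.04 (adjusted p = 0.940). The intervals and floors given for counts cover counting error only.

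The count of 316 for OO against chow became 208, 209, 145, 165 and 174 without chow 2, 3, 4 and 5 and OO 3, and 122 with only the chow and OO libraries in the fit. With library totals in place of composition factors, the median of all genes moved by -0.186 and the calls were 62 higher and 162 lower. Of the 62 called genes named here, 24 lost the call when some library was left out and 42 without the 4 libraries with muscle transcripts.

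SFO livers, compared with chow, had higher acute phase and protein folding transcripts and lower transcripts of xenobiotic metabolism and PPAR alpha targets. Serum amyloid genes Saa1 (5.76 ± 0.99, adjusted p = 0.00386) and Saa2 (5.53 ± 1.01) rose most. Of 23 acute phase genes, 14 rose and none fell. Within the list, 20 rose adjusted over the list alone (median 1.24, camera adjusted p = 1.10e-45, adjusted p = 0.000441 with an estimated correlation). They included Serpina3n (1.60 ± 0.19), haptoglobin Hp (1.35 ± 0.19) and the fibrinogen chains Fgg and Fgb (both 0.94 ± 0.12). The level varied between SFO libraries: Saa1 was at 355, 72.3, 500.7, 219 and 26.3 CPM in SFO 1, 2, 3, 5 and 6, against 4.40 ± 1.95 in chow (n = 6). Of 19 genes of the unfolded protein and integrated stress response, 6 rose and none fell. Within the list, 9 rose adjusted over the list alone (median 0.62, camera adjusted p = 1.02e-11, adjusted p = 0.00690 with an estimated correlation). The called genes included chaperones and folding factors of the endoplasmic reticulum, Manf (1.48 ± 0.34), Pdia4 (0.76 ± 0.18), Creld2 (1.65 ± 0.40) and Hsp90b1 (0.62 ± 0.15).

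Xenobiotic genes fell in SFO in 9 of 25 cases and rose in none. Within the list, 14 fell and 1 rose adjusted over the list alone (median -0.92, camera adjusted p = 1.21e-30, adjusted p = 1.30e-05 with an estimated correlation). Gstm1 fell by 1.60 (SE 0.13), Cyp2c29 by 1.63 (SE 0.16), Ces2a by 1.44 (SE 0.15) and Cyp3a11 by 2.87 (SE 0.31). Of 16 NRF2 targets, Ephx1 (-1.52 ± 0.18), Gclc (-1.02 ± 0.16), Gsta4 (-2.26 ± 0.46) and Gsta2 (-3.61 ± 0.93) fell and none rose, also 4 adjusted over the list alone (median -0.50, camera adjusted p = 2.87e-11, adjusted p = 3.03e-05 with an estimated correlation). Of 23 PPAR alpha targets, 6 fell and none rose. Within the list, 9 fell adjusted over the list alone (median -0.59, camera adjusted p = 2.87e-11, adjusted p = 0.00503 with an estimated correlation). Cyp4a14, a fatty acid ω-hydroxylase, fell from 378 ± 90.0 CPM in chow (n = 6) to 17.7 ± 12.1 in SFO (n = 5). Acot1 fell by 2.73 (SE 0.55), Ehhadh, a peroxisomal β-oxidation enzyme, by 0.91 (SE 0.17) and Acaa1b by 1.04 (SE 0.22). Cholesterol genes rose in 5 of 24 cases and fell in none, among them Sqle (1.23 ± 0.23), Msmo1 (0.78 ± 0.18), Cyp51 (0.69 ± 0.17) and Fdft1 (0.96 ± 0.24). Within the list, 10 rose adjusted over the list alone (median 0.63, camera adjusted p = 9.82e-14, adjusted p = 0.0113 with an estimated correlation). Of 19 fatty acid synthesis genes Elovl5 (0.70 ± 0.14) and Fads2 (0.79 ± 0.16) rose, and 4 adjusted over the list alone (camera adjusted p = 0.00574, adjusted p = 0.353 with an estimated correlation). Slc10a2 (2.23 ± 0.40), Slc22a7 (2.31 ± 0.45), Atp11a (2.63 ± 0.61), Scara5 (2.54 ± 0.55) and Lcn2, lipocalin 2 (4.97 ± 1.24), were other large rises. The rise of Lcn2 ran from 4.39 to 7.44 with 1 library left out, lost the call for 9 of the libraries and was 8.28 ± 1.69 without the 4 libraries with muscle transcripts. The muscle gene Hspb7 had 0 counts in all 5 SFO libraries and was at least 124-fold lower than in chow, while Myot and Casq1 had 1 count each, ratios of 873 (156 to 34522) and 596 (107 to 23569). Ldhb was at 0.175 CPM against 8.74 in chow, a difference of -5.60 ± 1.44 that was -4.25 ± 1.83 (adjusted p = 0.912) without the 4 libraries with muscle transcripts. Hspb7, Myot and Casq1 had too few counts to be tested without them. Cyp3a44 fell by 3.89 (SE 0.88).

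The count of 100 for SFO against chow became 64, 60 and 59 without chow 5, SFO 1 and SFO 5. Of the 46 called genes named here, 22 lost the call when some library was left out and 23 without the 4 libraries with muscle transcripts, among the latter Saa1, Saa2 and Cyp4a14. With 3 chow libraries left their fold changes stayed about as large and their SE grew, to 5.46 ± 1.45 for Saa1 (adjusted p = 0.305), 5.33 for Saa2 (adjusted p = 0.382) and -4.49 ± 0.96 for Cyp4a14 (adjusted p = 0.0837). With all libraries Cyp4a14 was at -4.43 ± 0.81.

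The difference of the cottonseed oil diet from the other oil diets, the question of the design, showed most clearly in the PPAR alpha targets. Of 23 measured, 10 were higher in CSO than in the mean of OO and SFO and none lower. Within the list, 13 were higher adjusted over the list alone (median 0.85, camera adjusted p = 6.11e-26, adjusted p = 0.000124 with an estimated correlation). Cyp4a14 was at 611 ± 261 CPM in CSO (n = 6), 76.6 ± 72.1 in OO (n = 6) and 17.7 ± 12.1 in SFO (n = 5), a difference of 4.06 ± 0.58 (adjusted p = 0.000662). Acot1 was higher by 2.38 ± 0.41, Pex11a by 1.25 ± 0.18 and Aldh3a2 by 0.83 ± 0.14. The clock score was 3.92 ± 0.64 in CSO (n = 6), 1.21 ± 1.54 in OO and 1.70 ± 2.37 in SFO, and with it as a covariate the median of the list was 0.68 and Cyp4a14 differed by 3.92 (adjusted p = 0.0270). All 16 mitochondrial fatty acid oxidation genes had a positive difference, with Eci1 called (0.83 ± 0.21) and 6 adjusted over the list alone (median 0.32, camera adjusted p = 2.41e-06, adjusted p = 0.0209 with an estimated correlation). The 21 lipid uptake and droplet genes had 0 calls over all genes and 5 rises adjusted over the list alone (median 0.38, camera adjusted p = 0.00152, adjusted p = 0.0296 with an estimated correlation). Por was higher by 1.17 ± 0.16 and Gpat3, an enzyme of glycerolipid synthesis, by 3.16 ± 0.61, and Gmnn, Slc16a5, Cyp4a10 and Acot4 were also higher (3.26, 2.60, 1.94 and 1.85).

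Acute phase genes were lower in CSO than in the mean of the other oils in 4 of 23 cases and higher in none. Within the list, 15 were lower adjusted over the list alone (median -0.66, camera adjusted p = 4.20e-18, adjusted p = 0.0296 with an estimated correlation). Fgg (-0.76 ± 0.11), Fgb (-0.64 ± 0.11), Fga (-0.66 ± 0.12) and Lbp, a lipopolysaccharide-binding protein (-1.05 ± 0.24), were lower in CSO than in the other oils. The mean of the acute phase list was 5.68 log2 CPM in chow, 6.00 in CSO, 6.18 in OO and 7.44 in SFO. The mean of the list was thus above chow in all 3 oil diets, by least in CSO and by most in SFO. Single libraries ran from 5.38 to 5.96 in chow, 5.77 to 6.26 in CSO, 5.55 to 7.04 in OO and 6.10 to 8.21 in SFO. Of 17 bile acid genes, Abcb11 (-0.79 ± 0.13), Hsd3b7 (-0.72 ± 0.12) and Cyp2c70 (-0.69 ± 0.17) were lower and none higher, also 3 adjusted over the list alone (camera adjusted p = 0.00390, adjusted p = 0.155 with an estimated correlation). Slc30a10 was at 14.4 ± 2.73 CPM in CSO (n = 6), against 50.2 ± 9.78 in chow (n = 6), 68.1 ± 24.6 in OO (n = 6) and 54.3 ± 37.7 in SFO (n = 5). Angptl8, a regulator of lipoprotein lipase, was lower by 1.92 (SE 0.42), Ppp1r3c, a glycogen-targeting phosphatase subunit, by 2.36 (SE 0.43), Chka, a choline kinase, by 2.21 (SE 0.40), Cldn1, a tight junction protein, by 1.44 (SE 0.25) and Mlxipl, the carbohydrate response factor, by 0.82 (SE 0.18). Ccn1, Avpr1a and Elovl3 were lower as well (-2.04, -1.54 and -1.53).

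The count of 87 became 53, 57 and 56 without CSO 4, 5 and 6, 55 with only the oil diets in the fit and 23 with the clock score as a covariate. With library totals in place of composition factors the calls were 73 higher and 28 lower in CSO, against 41 and 46. The median of all genes then moved by 0.0932. Of the 36 called genes named here, 16 lost the call when some library was left out and 24 with the clock score, where the Acot1 difference was 2.25 (adjusted p = 0.0545).

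Set against each oil alone, PPAR alpha targets were higher in CSO than in OO in 5 of 23 cases, 8 adjusted over the list alone (median 0.76, camera adjusted p = 2.73e-09, adjusted p = 0.0313 with an estimated correlation). They were higher than in SFO in 9 of 23, 14 adjusted over the list alone (median 0.89, camera adjusted p = 5.52e-27, adjusted p = 0.000116 with an estimated correlation). None was lower in either. Against OO, Por was higher (1.28 ± 0.19) and Abcb11 (-1.12 ± 0.14), Hsd3b7 (-1.07 ± 0.13) and Gclc (-1.05 ± 0.15) were lower in CSO. Fatty acid synthesis genes were lower in CSO than in OO in 2 of 19 cases, Elovl5 and Mlxipl. Within the list, 6 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00149, adjusted p = 0.287 with an estimated correlation). Against SFO, Aldh3a2 was higher by 1.39 ± 0.18, and so was Acaa1b. Mitochondrial oxidation genes were higher than in SFO in 2 of 16 cases and 6 adjusted over the list alone (camera adjusted p = 1.06e-09, adjusted p = 0.00242 with an estimated correlation). Acute phase genes were lower than in SFO in 8 of 23 cases and 19 adjusted over the list alone (median -0.88, camera adjusted p = 5.82e-33, adjusted p = 0.00249 with an estimated correlation). Stress response genes had 0 calls against SFO and 8 lower adjusted over the list alone (median -0.51, camera adjusted p = 2.13e-07, adjusted p = 0.0332 with an estimated correlation). The largest differences from OO were Epop (7.31 against 0.0935 CPM), Rexo5 (3 counts in OO, a ratio of 86.0 with a counting interval of 29.2 to 419) and Rasgrp3 (3.67 against 0.0817 CPM), higher in CSO, and Zbtb7c (-4.12), Gdf15 (-3.90) and Adamts7 (-3.14), lower. Those from SFO were Cyp4a14 (5.12), Acot1 (2.75) and Cyp4a10 (2.69), higher in CSO, and Saa2 (-4.91), Saa1 (-4.30) and Mt2, a metallothionein (-3.80), lower. The count of 130 against OO became 62, 74 and 70 without CSO 1, 4 and 6, 260 without OO 5 and 83 with library totals (49 higher, 34 lower, the median of all genes moving by 0.156). That of 59 against SFO became 38, 33, 30 and 31 without CSO 4, 5 and 6 and SFO 5. Of the 32 called genes chosen for naming against OO, 20 lost the call when some library was left out, 19 without the 4 libraries with muscle transcripts and 23 with the clock score, among the last Epop, Rexo5, Rasgrp3, Zbtb7c, Gdf15 and Adamts7. Of the 24 against SFO, 11, 10 and 13 did.

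**Figure D5:**
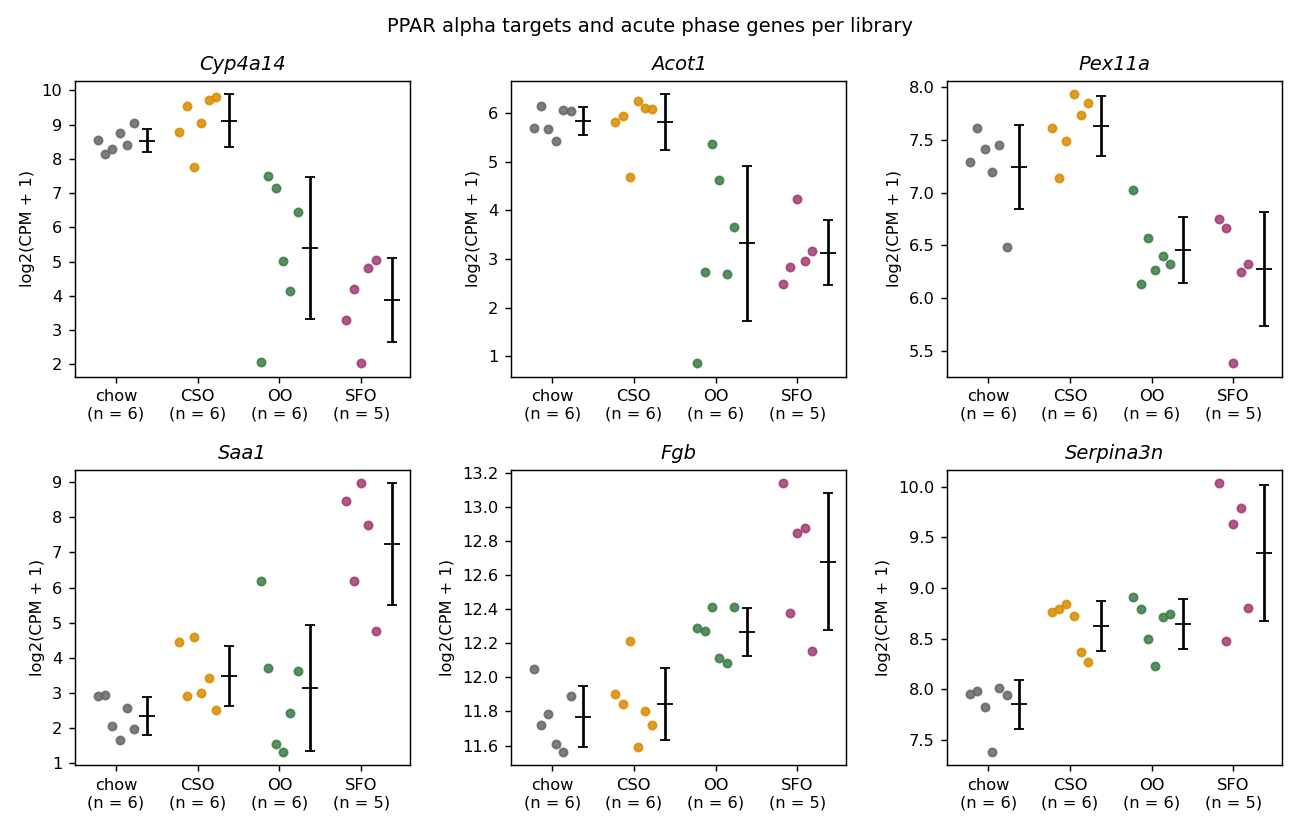
Log2(CPM + 1) of the PPAR alpha targets Cyp4a14, Acot1 and Pex11a and the acute phase genes Saa1, Fgb and Serpina3n, by diet, with axes not from 0; each point is a library and the black bars are the mean and SD. Cyp4a14, Acot1 and Pex11a are lowest in OO and SFO, and the acute phase genes are highest in SFO.

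SFO and OO livers, compared as a measure of how far the oils other than cottonseed differ, parted in detoxification and bile acid genes. Gclc (-1.12 ± 0.16), Cyp2c29 (-0.91 ± 0.16), Gstt3 (-2.10 ± 0.39) and Aldh3a2 (-1.11 ± 0.18) were lower in SFO. Xenobiotic genes were lower in SFO in 4 of 25 cases and higher in none. Within the list, 9 were lower adjusted over the list alone (median -0.51, camera adjusted p = 9.10e-07, adjusted p = 0.0400 with an estimated correlation). NRF2 targets were lower in 1 of 16 and 3 adjusted over the list alone (median -0.46, camera adjusted p = 0.000211, adjusted p = 0.0300 with an estimated correlation). Of 17 bile acid genes, 5 were lower in SFO, among them Hsd3b7 (-0.70 ± 0.14) and Abcb11 (-0.66 ± 0.15). Within the list, 7 were lower and 1 higher adjusted over the list alone (camera adjusted p = 9.88e-05, adjusted p = 0.0961 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, was at 5707 ± 2451 CPM in SFO (n = 5) and 14057 ± 4207 in OO (n = 6). It was the only fatty acid synthesis gene of 19 called over all genes (-1.30 ± 0.27). Within the list, 8 were lower adjusted over the list alone (camera adjusted p = 4.08e-07, adjusted p = 0.103 with an estimated correlation). Acute phase genes were higher in SFO than in OO in 6 of 23 cases and 12 adjusted over the list alone (camera adjusted p = 1.15e-10, adjusted p = 0.103 with an estimated correlation). Dok3 had 0 counts in all 6 OO libraries and was at least 108-fold higher in SFO, where it varied widely (5.56 ± 8.42 CPM, n = 5). Tgfbr3l and BC021767 were at 15.9 ± 24.0 and 9.81 ± 8.32 CPM in SFO (n = 5) against 0.186 and 0.173 in OO. Tgfbr3l was at 57.6 CPM in SFO 2, and all of its OO counts lay in OO 5. Rpain, Tusc3 and Tecpr2 were lower in SFO (-2.63, -2.55 and -2.40), but by as little as -1.37, -2.14 and -1.57 with 1 library left out. The detected genes were fewest in OO, as given above. The count of 127 became 78, 84, 53, 72 and 31 without OO 2, OO 3, SFO 1, SFO 3 and SFO 5, 240 without OO 5, 56 with library totals (33 higher, 23 lower, the median of all genes moving by 0.128) and 2 with only these diets in the fit. Of the 32 called genes chosen for naming, 23 lost the call when some library was left out and 17 without the 4 libraries with muscle transcripts, Rpain, Tusc3 and Tecpr2 in both cases, and 2 kept it under every setting. None of those 4 libraries is an SFO or OO library. Leaving them out alters the genes tested (12371 in place of 11971), the composition factors and the spread shared with the other diets.

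Genes chosen in advance for their place in lipid metabolism were often uncalled. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and Fgf21, Angptl4, Cd36, Ppara and Ppard passed the test in no comparison. Cyp7a1 was at 212 ± 79.3 CPM in chow (n = 6), 216 ± 69.7 in CSO (n = 6), 154 ± 40.7 in OO (n = 6) and 126 ± 87.3 in SFO (n = 5). Scd1 in CSO differed from chow by -0.24 ± 0.25 and passed the test only between SFO and OO, and Srebf1 (0.93 in CSO, adjusted p = 0.0616) and Fasn passed it only in OO against chow.

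Sex-biased liver genes, whose levels follow growth hormone secretion, moved in few members. Of 18 male-biased genes, Elovl3 fell in CSO, Cyp4a12a (-1.16 ± 0.21) fell in OO, and in SFO Mup20 rose and Cyp4a12a (-1.04 ± 0.22) and Cyp4a12b fell. Of 7 female-biased genes, Cyp3a44 fell in OO (-4.60 ± 0.85) and in SFO, where the list passed the test (median -0.99, camera adjusted p = 0.00338, adjusted p = 0.0317 with an estimated correlation). Of 17 clock genes, Nr1d1 (a repressor of the clock) fell in CSO and Usp2 (a ubiquitin protease under clock control) fell in OO (-3.12 ± 0.69). None was called in SFO, and against chow the list passed the test only in CSO (camera adjusted p = 0.0397, adjusted p = 0.336 with an estimated correlation). Of 19 glucose metabolism genes, Pcx, which makes oxaloacetate from pyruvate, rose in CSO and in OO (0.64 ± 0.14), and none was called in SFO. Of 15 periportal genes, Pigr rose and Cyp2f2 fell in OO, and Cyp2f2 and Etnppl fell in SFO. Cell cycle (14 measured), nuclear-encoded respiratory chain (21), fibrosis and stellate cell (19), Kupffer cell and macrophage (17), sinusoidal endothelial (16), cholangiocyte (8) and B cell (6) genes had 0 calls against chow. Endothelial markers passed the list test downward in CSO, OO and SFO (camera adjusted p = 0.0294, 0.00562 and 0.0141), with adjusted p = 0.336, 0.238 and 0.260 with an estimated correlation.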

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

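The rule was set before the data were examined, and each value below is the highest or lowest of its group with a gap to the nearest other library that takes up most of the range of the group. The rule was applied to 128 groups of values and marked 6, and chance marks about 1 group in 20. Fads2 was at 2231 CPM in OO 2, with the other OO libraries at 1388 to 1518 CPM. Fasn was at 1147 CPM in SFO 6, with the others at 514 to 643 CPM. Srebf1 was at 93.6 CPM in chow 1, with the others at 152 to 192 CPM, and Cyp7a1 in the same library was at 68.0 CPM, with the others at 184 to 283 CPM. Lcn2 was at 4.73 CPM in chow 3, with the others at 0 to 0.305 CPM. Acot1 was at 24.8 CPM in CSO 3, with the others at 55.3 to 74.9 CPM.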

How the results depend on the processing

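The fits without the 4 libraries with muscle transcripts, with the clock score, with thinned counts and with genes and factors kept were chosen after seeing the data, and the other settings before. Values run in the order CSO, OO and SFO against chow, CSO against the mean of OO and SFO, CSO against OO, CSO against SFO, and SFO against OO, with 49, 316, 100, 87, 130, 59 and 127 genes changed. No setting reversed the direction of a named gene called in the main fit. Lists were not tested again with DESeq2's test, voom, thinned counts, other filters, 1 library left out or only the diets of the comparison. In the settings where they were, no list that passed the test passed it in the other direction, but many lost the test. Of the 14, 13, 11, 11, 10, 11 and 12 lists that passed it, 4, 6, 7, 5, 1, 7 and 2 still did with an estimated correlation and 6, 10, 7, 5, 5, 9 and 8 by fry. With the clock score 10, 13, 11, 8, 6, 8 and 12 did, and without the 4 libraries with muscle transcripts 13, 12, 11, 10, 8, 11 and 12. DESeq2 gave 111, 686, 187, 196, 413, 140 and 440 genes. Voom gave 215, 125, 148, 189, 110, 148 and 20, and only the diets of the comparison gave 198, 122, 109, 55, 79, 91 and 2, or 192, 199, 117, 69, 83, 90 and 10 with the genes and composition factors of all libraries kept. An absolute log2 fold change of at least 1 left 17, 162, 57, 48, 76, 34 and 69. Without the 4 libraries with muscle transcripts there were 14 (13 shared), 26 (26), 34 (33), 42 (40), 40 (40), 39 (37) and 37 (37) genes. With the clock score there were 23 (17 shared), 338, 104, 23 (19), 41 (31), 27 (24) and 145. Thinned counts gave 50, 289, 100, 86, 122, 62 and 114. DESeq2's size factors and the other filters moved no count by more than 1.5 times. With library totals the OO against chow calls split 62 higher and 162 lower (206 and 110 with TMM), CSO against the mean 73 and 28 (41 and 46), CSO against OO, 83 in all, 49 and 34 (30 and 100) and SFO against OO, 56 in all, 33 and 23 (32 and 95), and the cause was not tested.

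The replicate number as a block gave 208 genes for OO against chow and 77 for SFO against OO. Libraries of the same number had correlations of -0.101 to 0.0346 once group means were removed, 0 of 33 pairs were over 0.1, and 1 of 23 libraries correlated best with its own number. With chow split 3 and 3, the median number of shared calls over 20 splits was 8 for CSO and OO, 9 for CSO and SFO and 13 for OO and SFO. The SFO_4 alternative was not run, as the count table has no such column. Leaving out each library gave 22 to 45, 145 to 471, 59 to 87, 53 to 116, 62 to 260, 30 to 77 and 31 to 240 genes. For CSO against chow the counts were 26, 29, 25 and 29 without chow 1 to 4 and 31, 28, 23, 30 and 22 without CSO 1, 3, 4, 5 and 6. For OO against chow they were 208, 209, 145 and 165 without chow 2 to 5 and 174 without OO 3. For SFO against chow they were 64, 60 and 59 without chow 5, SFO 1 and SFO 5. For CSO against the mean they were 53, 57 and 56 without CSO 4 to 6. For CSO against OO they were 62, 74 and 70 without CSO 1, 4 and 6 and 260 without OO 5. For CSO against SFO they were 38, 33 and 30 without CSO 4 to 6 and 31 without SFO 5. For SFO against OO they were 78, 84 and 240 without OO 2, 3 and 5 and 53, 72 and 31 without SFO 1, 3 and 5.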

Other observations

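The tests of clock phase, of skeletal muscle tissue, of depth, of group size and of other groupings were written before their results were seen, and those of gene detection, fasting and shared spread after. Among sex-biased genes, Cyp4a12a (0.95 ± 0.17) and Cyp4a12b (1.11 ± 0.19), male-biased ω-hydroxylases, were higher in CSO than in the mean of OO and SFO and Elovl3 was lower (-1.53), while Hsd3b5, a male-biased steroid dehydrogenase, was lower in CSO than in OO (-1.11 ± 0.21) and lower in SFO than in OO (-0.87 ± 0.22). The major urinary protein genes Mup20 (0.89 ± 0.18) and Mup1 were higher in SFO than in OO. Of the 18 male-biased genes, 2 were higher and none lower in CSO than in SFO although the list test pointed down (median -0.25, camera adjusted p = 0.0244, adjusted p = 0.562 with an estimated correlation). The 7 female-biased genes had 0 calls between CSO and SFO, with a list test that pointed up (median 1.08, camera adjusted p = 0.00288, adjusted p = 0.0315 with an estimated correlation).

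Among clock genes, Nr1d1 was at 61.3 ± 15.98 CPM in CSO (n = 6) and 160 ± 56.4 in OO (n = 6), a difference of -1.38 ± 0.24, and Usp2 at 83.5 ± 22.4 and 5.89 ± 6.34, a difference of 3.82 ± 0.71. Mt2, a metallothionein induced by metals and inflammation, was at 64.9 ± 66.1 CPM in SFO (n = 5) and 3.40 ± 3.14 in OO (n = 6), a difference of 4.25 ± 0.86. Steap4, a metalloreductase induced in inflammation, was at 448 ± 264 and 156 ± 55.1 CPM in the same groups (1.52 ± 0.34). Col4a2, a basement membrane collagen, was the only fibrosis list gene of 19 called, higher in SFO than in OO (1.82). Of the cell-type markers too few to test, the adipocyte marker Fabp4 fell in OO against chow (-3.74 ± 0.99), and was at -2.82 ± 1.20 (adjusted p = 0.416) without the 4 libraries with muscle transcripts. None of the T and NK cell, neutrophil, erythroid or exocrine pancreas markers was called in any comparison.

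Skeletal muscle genes lower in OO and SFO than in chow may come from muscle tissue collected with some of the chow livers or from an effect of diet. Muscle genes not looked at before averaged 13.963 times as high in chow 3, chow 4, chow 5 and CSO 1 as in the other 19 libraries, which fits tissue in those samples. A diet effect in every chow liver would place all 6 chow libraries above the OO and SFO libraries, but 3 lay within their range. The top of that range was SFO 2, with a mean of 7.27 CPM for these genes. The OO libraries ran from 1.65 to 3.22 CPM, below chow 2 (3.64) and chow 6 (4.18). Against OO alone the result therefore rests on chow 1 (1.14 CPM). Muscle in the tissue taken remains the simplest reading, though the counts cannot tell when it entered. Histology of the same livers, or counts from other lobes, would tell these apart.

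PPAR alpha targets higher in CSO than in OO and SFO may come from a rise in CSO, from a fall in OO and SFO, from clock phase at collection or from fasting. The mean of the list was 6.59 log2 CPM in chow, 6.89 in CSO, 5.76 in OO and 5.47 in SFO, so most of the difference in means was a fall below chow in OO and SFO. The median changes from chow were 0.23 in CSO, -0.07 in OO and -0.59 in SFO. With the clock score as a covariate the list's median was 0.676895, against 0.85 without it, and the list still passed the test (adjusted p = 0.00198 with an estimated correlation), so phase as measured by this score was excluded as the whole cause, while the score itself differed with diet. Low gene detection in OO was excluded as the whole cause, as the median against SFO alone was 0.893666. That comparison holds no OO library, so a part in the difference from OO stays open. Fasting in the CSO animals alone stays open. The 7 fasting-induced genes outside the list went both ways, from Igfbp1 (-1.13) to Ppargc1a (0.65), with a median of -0.0495756 and an SD of 0.57, which reaches past the 0.43 set as the least that fasting would need. Receptor activity was not tested. Receptor binding would test it, and livers collected at several times of day would test phase.

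More genes changed against chow in OO (316) than in SFO (100), which may reflect the diets, the libraries or the fit. Among abundant genes 191 changed in OO against 76 in SFO, so genes missed for low expression were not the whole cause. Those counts used composition factors that were lowest in OO (mean 0.923, against 1.01 in SFO). An effect of low detection through these factors therefore stays open. With library totals the counts were 224 and 97, and the OO calls were 62 higher and 162 lower. Depth was excluded as the whole cause (289 against 100 after thinning). So was group size (at least 174 against 100 with 1 OO library left out, the lowest without OO 3). Fitted with only the diets of each comparison the counts were 122 and 109, but fewer genes were then tested (10419 and 11013). With the genes and composition factors kept they were 199 and 117, so the spread shared with the other diets stays open as part of the cause. Voom (125 against 148) and the fit without the 4 libraries with muscle transcripts (26 against 34) turned the order. The order of these counts is therefore not evidence that olive oil had the larger effect.

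None of the 99 other groupings of 100 reached the real count in any comparison. The other groupings mix the diets, which adds real differences to the spread and can lower their counts. The test therefore does not exclude chance for each comparison. SFO against OO, for one, had only 2 genes with only these diets in the fit. The real counts and highest others were 49 and 6 for CSO against chow, 316 and 4 for OO, 100 and 20 for SFO, 87 and 9 for CSO against the mean of OO and SFO, 130 and 76 for CSO against OO, 59 and 19 for CSO against SFO, and 127 and 78 for SFO against OO.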
